A study of Mus musculus with 2 samples.

How the data were processed

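The 2 deposited count matrices hold counts, that is unnormalised UMI counts per gene and cell barcode per the file headers, and the deposited barcode and gene lists beside them hold names. Cell Ranger 7.2.0 and the GRCm39 genome are named in the file headers and the submitters' processing notes, and nothing upstream of the matrices was rerun. Each matrix covers 55357 genes. The smallest barcode total is 500 UMIs in both libraries, so emptier droplets were not analysed here and RNA shed into the suspension was judged only from cells that should not express a gene.

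Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed 78 barcodes of the AptCD4-LNT library and 39 of the Untreated library. Doublets were then removed per library with Scrublet at its automatic threshold, taking out 220 cells (2.485%) of the AptCD4-LNT library and 1665 (8.325%) of the Untreated library. The rate expected from the number of barcodes was 7.145% and 16.0%, and removal at that rate is among the alternatives tried. Counts were normalised to 10000 per cell and logged, 2000 variable genes were scaled, and 30 principal components with 15 neighbours gave 21 Leiden clusters at resolution 1, without any batch integration. The software was Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

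The marker sets of 19 cell classes and 5 T cell subsets, the 23 gene lists, the main settings and their alternatives were fixed before the data were examined. How marker scores became names was settled only after the clusters had been seen. A cluster took the class with the highest mean log2 level of its markers over the lower quartile of all clusters, if that score reached 1 and at least 3 markers stood at 20 CPM or more. A cluster led by genes of another class, by osteoclast genes, or by no marker of its own at very low depth was left unnamed. The unnamed clusters were cluster 9, with 2.24% of AptCD4-LNT cells and 2.37% of Untreated cells, cluster 16, with 0.498% and 4.85%, and cluster 19, with 0.266% and 0.158%. The T and NK cluster was split into 12 sub-clusters, and only those with CD3 and T cell receptor genes near the highest level were called T-like. That left 41 of 154 cells (26.6%) of the AptCD4-LNT part and 114 of 596 (19.1%) of the Untreated part in sub-clusters that were neither T-like nor NK-like.

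Gene levels are CPM, the UMIs of a gene per 1000000 UMIs summed over a class, and ratios are AptCD4-LNT over Untreated on the log2 scale. Classes with at least 50 cells in each library were compared. Intervals are exact 95% binomial intervals for shares and for ratios of counts. Those for ratios of shares ignore that a share is bounded, so they are wider than needed where shares are large. Intervals of list medians, given only in the closing section, are the middle 95% of 1000 resamples of the list's members. A gene with 0 counts in 1 library is given as a bound of at least N-fold, taking 3 counts as the floor. A list is summarised by the median log2 ratio of its members with 20 or more UMIs, if there were at least 4, and by its percentile among 10000 random lists matched on expression. Genes outside the lists were chosen by a fixed rule, the largest ratios whose interval excluded 0 among genes with at least 30 UMIs and 50 CPM, up to 10 in each direction. For 2 genes of other lists single values are not reported here. Other genes named without a list are said to have been chosen after their values were seen.

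Scaling to the total left a shift of more than 0.1 in 2 of the 7 classes. Over genes with 100 or more UMIs the median log2 ratio was 0.18 in macrophage-like cells and 0.13 in neutrophil-like cells. Shares of T-like cells with a UMI of a gene were also taken after thinning each cell to 1000 UMIs, which leaves out 1 and 140 T-like cells and 69 and 274 epithelial-like cells of the AptCD4-LNT and Untreated libraries below that depth. The calculation was checked on simulated Poisson counts, the model that the intervals assume, in which 200 genes per class were changed. Intervals covered the set ratio for 95.1% to 96.1% of genes, and 3 to 8 of 100 unchanged lists fell outside the middle 95% of random lists. The simulated genes were independent and did not vary between cells or libraries. The check therefore says nothing on such variation or on lists whose genes vary together. In 1 of the named T cell lists, that for Th2 and Th17 genes, only Gata3 and Il17a reached 20 UMIs, so no median is given for it.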

Results

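Tumours grown from 4T1 cells, a triple-negative mouse breast cancer line, were profiled by single-cell RNA sequencing in BALB/c mice given AptCD4-LNT or PBS. AptCD4-LNT was dosed by cell number in 3 doses spaced 3 days apart, tissue was taken at day 9, and 3 tumours were mixed into each library. The series title sets out to mobilise and activate CD4+ T cells, so the comparison of the AptCD4-LNT library with the Untreated library asks first how many T cells the tumours held, of which kind, and with which activation genes, and then how the tumour, myeloid and stromal cells around them differed. The AptCD4-LNT library held 8931 barcodes with 98968100 UMIs and a median of 8612 UMIs and 2920 genes per barcode. The Untreated library held 20040 barcodes with 131295224 UMIs and a median of 4640.5 UMIs and 1967 genes. After filtering, 8633 AptCD4-LNT and 18336 Untreated cells were kept, with a median of 8589 and 4482 UMIs. There are no replicates, so no difference was tested against variation between mice or libraries. Every interval is a 95% interval. Those of shares and of ratios of counts cover counting error only, and those of list medians cover only the spread among list members.

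T-like cells were scarcer in the AptCD4-LNT library. They made up 73 cells or 0.846% (0.663 to 1.06%) of it and 473 cells or 2.58% (2.36 to 2.82%) of the Untreated library, a 3.05-fold lower share (2.38 to 3.96). Among haematopoietic cells alone, which were 44.2% of AptCD4-LNT and 40.6% of Untreated cells, the T-like share was 1.91% against 6.36%. CD8 T-like cells, the cytotoxic lineage, accounted for nearly all of the gap, with 50 cells (0.579%) against 420 (2.29%), a share 3.955-fold lower (2.945 to 5.415). CD4 T-like cells numbered 14 (0.162%, 0.0887 to 0.272%) against 47 (0.256%, 0.188 to 0.341%), a ratio of 0.633 whose interval of 0.322 to 1.17 includes 1. Counting the whole cluster of T and NK cells instead gave 1.78% against 3.25%, a 1.82-fold lower share. T-like cells were deeper in the AptCD4-LNT library, at a median of 2700 UMIs against 1569, and a stricter filter kept 100% of them against 82.7% of the Untreated ones.

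Innate lymphocytes ran the other way. NK-like cells, which kill without antigen receptors, were 40 cells (0.463%) of the AptCD4-LNT library against 9 (0.0491%), a 9.44-fold higher share (4.51 to 22.1), and 26.0% against 1.51% of the T and NK cluster. Gamma-delta T-like cells, a lineage known for fast IL-17 release, numbered 9 against 6, or 0.104% and 0.0327% of cells, a ratio of 3.19 with an interval of 1.01 to 10.9. An unnamed sub-cluster led by Calca, Il1rl1, Areg and Csf2 held 23 against 7 cells, a 6.98-fold higher share (2.90 to 19.3). The other unnamed sub-clusters went both ways, with 3 against 76 cells in 1 led by epithelial genes, 2 against 23 in 1 led by neutrophil genes, 6 against 0 in 1 led by Cma1 and 7 against 8 in 1 led by Il6 and Il4.

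**Figure D1:**
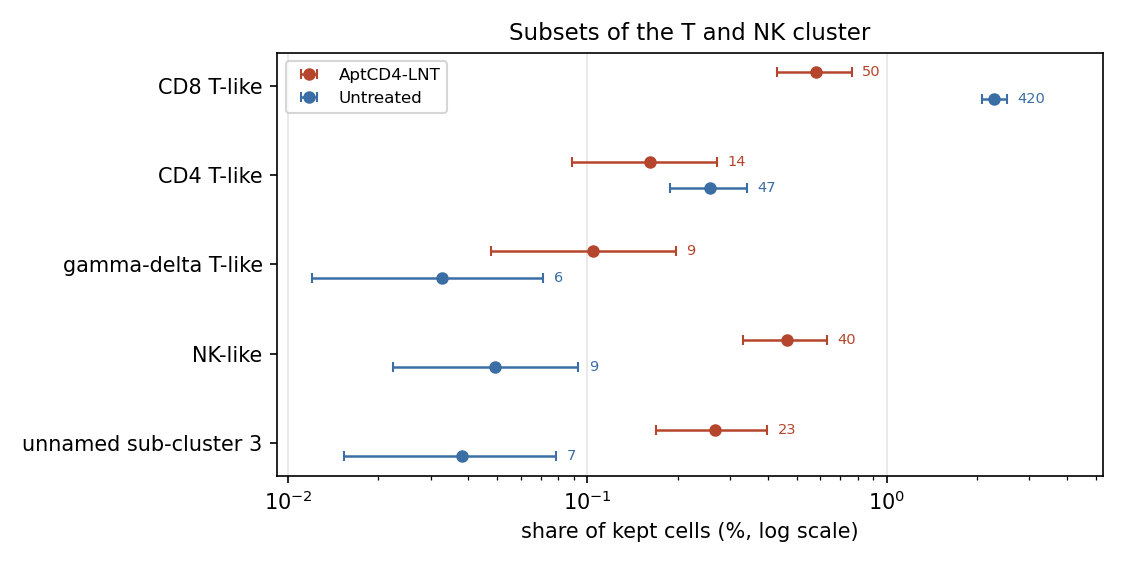
Share of kept cells of each library in the CD8, CD4 and gamma-delta T-like cells, the NK-like cells and the unnamed sub-cluster led by Calca. The axis is a log axis, with exact 95% intervals. The other unnamed sub-clusters are not drawn. CD8 T-like cells are lower and NK-like cells higher in the AptCD4-LNT library.

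The balance of CD4 and CD8 cells among T-like cells rests on few CD4 cells. CD4 T-like cells were 19.2% (10.9 to 30.1%) of T-like cells against 9.94% (7.39 to 12.99%), a ratio of 1.93 with an interval of 0.981 to 3.57. A finer split of the same cells gave a log2 ratio of -0.37 in place of 0.95, so no direction is given for CD4. CD8 T-like cells were 68.5% (56.6 to 78.9%) of T-like cells against 88.8% (85.6 to 91.5%). These intervals do not overlap, although that of the ratio, 0.563 to 1.04, includes 1. Gamma-delta T-like cells were 12.3% against 1.27%. The Cd4 transcript itself, the co-receptor for MHC class II, stood at 26.2 CPM on 9 UMIs against 36.55 CPM on 41 UMIs in T-like cells, a log2 ratio of -0.48 (-1.71 to 0.58). Cells with Cd4 and no CD8 gene were 7 (9.59%) against 26 (5.50%), those with a CD8 gene and no Cd4 30 (41.1%) against 314 (66.4%), and those with neither 36 (49.3%) against 133 (28.1%). Cd8a, the CD8 co-receptor chain, was lower per UMI of T-like cells as well, at 318 against 549 CPM, a log2 ratio of -0.79 (-1.10 to -0.49). Foxp3, the lineage factor of regulatory T cells and a leading gene of the CD4 sub-cluster, was 4.36-fold higher, at 35.0 CPM on 12 UMIs against 8.02 CPM on 9 UMIs, a log2 ratio of 2.12 (0.75 to 3.55). The CD4 sub-cluster scored almost as high for regulatory T markers, 4.847, as for CD4 markers, 4.955.

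Thinned to 1000 UMIs per cell, Cd8a and Gzmb were seen in fewer and Foxp3 in more of the AptCD4-LNT T-like cells, but not at every depth. Cd4 was seen in 3 of 72 (4.17%) AptCD4-LNT and 16 of 333 (4.805%) Untreated T-like cells, and unthinned in 9.59% and 5.50%. Cd8a was seen in 23.6% against 42.6% thinned and in 38.4% against 51.8% unthinned, Foxp3 in 6.94% against 1.502% thinned and 6.85% against 1.48% unthinned. At 500 UMIs Foxp3 was left in 1 cell of each library, which gives no direction. Unthinned, the intervals of the ratios for Cd8a, 0.482 to 1.10, and Gzmb, 0.543 to 1.13, include 1. The granzyme gene Gzmb was seen in 38.9% against 61.3% thinned, and Ifng, the cytokine of type 1 responses, in 4.17% against 9.31%, a ratio whose interval of 0.0876 to 1.435 includes 1. Pdcd1, the gene of the PD-1 receptor, showed no detectable difference in the share of cells, at 20.8% against 22.8% thinned, a ratio of 0.913 (0.487 to 1.602). Mki67, a marker of dividing cells, switched order, at 9.72% against 14.1% thinned and 27.4% against 18.2% unthinned. Epithelial-like cells, which should hold none of these T cell genes and had a median of 17350 and 7086 UMIs beside 2700 and 1569 in T-like cells, gave Cd8a in 0.0264% and 0.0937% thinned and in 0.0777% and 0.253% unthinned, and Cd4 in none when thinned.

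Summed over each library, Cd8a, Ifng and Gzmb were lower, as CD8 T-like cells were, though Gzmc gave 2434 against 1620 UMIs in T-like cells. Cd8a was 1.24 CPM in the AptCD4-LNT library against 6.27 (log2 ratio -2.34), Ifng 0.294 against 1.64 (-2.48), Gzmb 15.4 against 50.2 (-1.70), and Cd274, which encodes the PD-L1 ligand, 22.5 against 70.8 (-1.66). Cd4 showed no detectable difference at this depth, at 0.441 CPM on 42 UMIs against 0.485 CPM on 55 UMIs, a log2 ratio of -0.14 (-0.75 to 0.47). Its source differed, since T-like cells held 9 of the 42 Cd4 UMIs in the AptCD4-LNT library and 41 of the 55 in the Untreated library, while macrophage-like cells held 12 and 4. Foxp3 gave 14 UMIs in each library.

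In T-like cells of the AptCD4-LNT library checkpoint genes took a lower and naive and memory genes a higher part of the UMIs, with no shift in the activation list. The T cell identity genes Cd3e, at 586 against 1033 CPM (log2 ratio -0.82), and Trac, at 248 against 661 (-1.42), were lower as well. The lower checkpoint genes, with a median close to the Cd3e ratio, therefore cannot be told apart from less T cell RNA in this class. Over the 8 measured checkpoint and exhaustion genes the median log2 ratio was -0.86, a 1.82-fold lower level at percentile 0.0 of matched random lists, and 5 genes were lower and 0 higher by 1.5-fold. Among them the inhibitory receptor genes Ctla4, at 254 against 452 CPM, Pdcd1, at 172 against 318, and Lag3, at 17.5 against 76.7 with a log2 ratio of -2.13 (-3.62 to -0.95), were lower, as was the ectonucleotidase Entpd1, at 35.0 against 127. Of naive and memory genes 4 of 8 were higher and 0 lower, with a median of 0.67 at percentile 99.8, including S1pr1, which lets T cells leave tissue, at 52.5 against 13.4 CPM. Il7r and Klf2, the most abundant of these, were at 338 against 395 and 324 against 262 CPM. Of the CD8 T-like cells behind these values, a sub-cluster led by Havcr2 and Klra5 held 2 AptCD4-LNT cells (2.74% of T-like cells) against 144 (30.4%), whereas a Tcf7-led sub-cluster held 34.25% of T-like cells in both.

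The T cell activation list centred on 0.03 (percentile 50.6, 3 of 10 genes higher and 2 lower). Tnfrsf9 and Icos, costimulatory receptors, were level at 632 against 605 and 318 against 316 CPM, while the early response genes Nr4a1, at 391 against 109 CPM, and Cd69, at 469 against 231, were higher. Dissociation stress could raise such early response genes as well, which was not tested in T-like cells. The median of Th1 and effector cytokine genes was -0.36 (percentile 1.17, 2 of 9 higher and 3 lower). Here Ccl5, a T cell attractant, was lower at 1035 against 1714 CPM, Ifng lower at 75.8 against 143 CPM with a log2 ratio of -0.91 (-1.57 to -0.31), and Tnf higher at 40.8 against 16.1. Il2, the T cell growth factor, gave 0 against 28 UMIs, at least 2.86-fold lower. Cytotoxic genes had a median of -0.30 (percentile 2.46, 3 of 10 higher and 3 lower) and split sharply. Gzmb was at 3870 against 4618 CPM, yet Gzmc, a granzyme of strongly stimulated killer cells, was 4.91-fold higher at 7093 against 1444, and Klrg1, found on short-lived effector cells, 8.53-fold higher (4.86 to 15.6) at 137 against 16.1. A CD8 sub-cluster led by the related Gzmd, Gzme, Gzmf and Gzmg held 17.8% of T-like cells against 7.19%. Regulatory T genes had a median of 0.52 (percentile 98.4, 3 of 6 higher and 1 lower), with Tnfrsf18, the costimulatory receptor GITR, at 312 against 129 CPM beside Foxp3. Homing receptors centred on 0.07 (percentile 61.9, 2 of 9 higher and 1 lower), with the chemokine receptors Ccr2, at 291 against 115 CPM, and Cxcr4, at 265 against 109, among the higher genes. Proliferation genes showed no direction at -0.00 (percentile 29.7, 0 of 12 higher and 2 lower), with Mki67 at 216 against 217 CPM.

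Immediate early and dissociation stress genes were the list furthest above Untreated levels in T-like cells, at a median of 0.96 (percentile 100, 7 of 12 higher and 0 lower), led by Junb, an AP-1 subunit, at 2028 against 948 CPM and by Fosb at 361 against 105. The list was also higher in macrophage-like (0.73), epithelial-like (0.65), monocyte-like (0.49) and neutrophil-like cells (0.46), less so in endothelial-like (0.22) and fibroblast-like cells (0.07). It is therefore not particular to T-like cells. Outside the lists, the stress gene Gadd45g was far higher, at 798 against 26.7 CPM, and Serpinb9b, a granzyme inhibitor family member, gave 0 against 70 UMIs, at least 7.14-fold lower. The type 2 factor Gata3 was at 125 against 51.7 CPM, and Il17a, which leads the gamma-delta sub-cluster, at 239 against 26.75.

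Interferon response genes were lower in the AptCD4-LNT library in the tumour, stromal and vascular cells but not in T-like cells. The median log2 ratio of the list was -0.96 in epithelial-like cells (percentile 0, 12 of 16 genes lower by 1.5-fold and 0 higher), -0.98 in fibroblast-like cells (percentile 0, 9 of 15 lower and 0 higher) and -1.08 in endothelial-like cells (percentile 0, 10 of 11 lower and 1 higher), or 1.95-fold, 1.97-fold and 2.11-fold lower. In T-like cells it was 0.51 (percentile 95.7, 3 of 9 higher and 0 lower). The interferon-induced GTPase gene Igtp was at 47.8 against 152 CPM in epithelial-like cells and at 10.3 against 42.4 in fibroblast-like cells. Untreated fibroblast-like cells also held more RNA of other classes. Krt8 in fibroblast-like cells was at 49.7 against 205.5 CPM and Lyz2 at 29.8 against 199.9. Part of the fibroblast difference may come from that RNA, which was not tested. Cxcl10, an interferon-induced attractant of effector T cells, was 17.8-fold lower (8.01 to 49.3) in endothelial-like cells, at 9.27 against 165 CPM on 6 against 159 UMIs. It was also lower in fibroblast-like, monocyte-like and neutrophil-like cells. In macrophage-like cells it was higher, at 206 against 168 CPM on 1267 against 1648 UMIs, a log2 ratio of 0.29 (0.19 to 0.40). Irf1 was nearly level in epithelial-like cells, at 272 against 264 CPM. Among the myeloid classes the list stood at -0.13 in macrophage-like cells (percentile 0.18, 1 of 16 higher and 1 lower, and -0.52 when each cell was weighted equally), -0.30 in monocyte-like cells (percentile 0.12, 2 of 16 higher and 5 lower) and 0.02 in neutrophil-like cells (percentile 21.7, 2 of 15 higher and 2 lower).

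**Figure D2:**
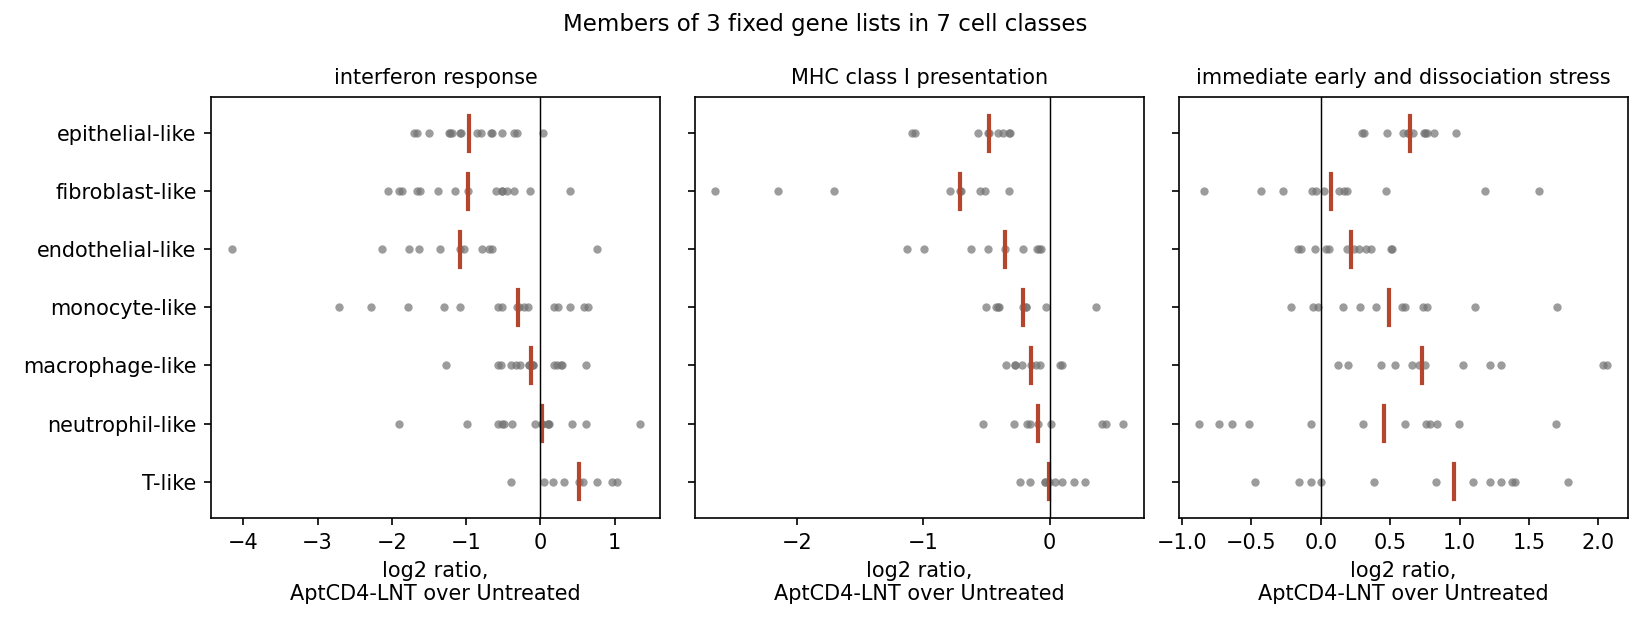
Log2 ratios of AptCD4-LNT over Untreated for each member of the interferon response, MHC class I and immediate early lists in 7 cell classes, with the median of each list as a line. The interferon medians are lowest in epithelial-like, fibroblast-like and endothelial-like cells.

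Antigen presentation genes were lower in the same 3 classes, most of all MHC class II in the tumour cells. In epithelial-like cells the class II list had a median of -1.41, a 2.66-fold lower level, with 8 of 8 genes lower (percentile 0). The invariant chain gene Cd74 was at 591 against 1455 CPM, a log2 ratio of -1.30 (-1.32 to -1.28), H2-Aa at 271 against 718, the peptide loading gene H2-DMb2 at 10.9 against 37.85, and Ciita, the master regulator of class II genes, at 6.72 against 16.3. The MHC class I list was -0.48 in epithelial-like cells (percentile 0, 2 of 9 lower and 0 higher), -0.71 in fibroblast-like cells (percentile 0.01, 6 of 9 lower and 0 higher) and -0.35 in endothelial-like cells (percentile 0.12, 3 of 9 lower and 0 higher). The classical class I gene H2-D1 was at 4455 against 5553 CPM in epithelial-like cells, and the immunoproteasome gene Psmb9 was 2.12-fold lower there (2.08 to 2.16) and 6.26-fold lower (5.13 to 7.67) in fibroblast-like cells. Part of the fibroblast gap may come from epithelial RNA, since Krt18 in these cells was at 55.3 against 271.5 CPM. This was not tested. Class I medians were -0.15 in macrophage-like cells (percentile 13.7), -0.21 in monocyte-like cells (percentile 2.79), -0.09 in neutrophil-like cells (percentile 12.0) and -0.00 in T-like cells (percentile 76.2), with 0 of 9 genes apart by 1.5-fold in any of them. Members differed, since in neutrophil-like cells H2-K1 was higher at 1987 against 1326 CPM and Psmb9 lower at 349 against 426. In endothelial-like cells H2-K1 was nearly level at 3710 against 3897 CPM, while Tap1 was lower at 85.0 against 169. Class II medians were -0.18 in macrophage-like cells (percentile 3.77, 2 of 8 lower and 0 higher), -0.24 in monocyte-like cells (percentile 1.81, 2 of 8 lower and 1 higher) and -0.46 in endothelial-like cells (percentile 1.57, 1 of 4 lower and 0 higher).

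Epithelial-like cells, which carry the tumour, made up 3859 cells (44.7%) of the AptCD4-LNT library and 9879 (53.9%) of the Untreated library. The largest epithelial cluster of the AptCD4-LNT library, cluster 10, held 38.1% of its epithelial-like cells and 6.195% of the Untreated ones, while cluster 6 held 7.02% and 26.3%. The lower interferon median was nevertheless present inside 6 of the 7 epithelial clusters, from -0.82 in cluster 6 to -1.29 in cluster 4. Cluster 17, which is led by Ifit genes and held 28 and 237 cells, had 0.18.

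**Figure D3:**
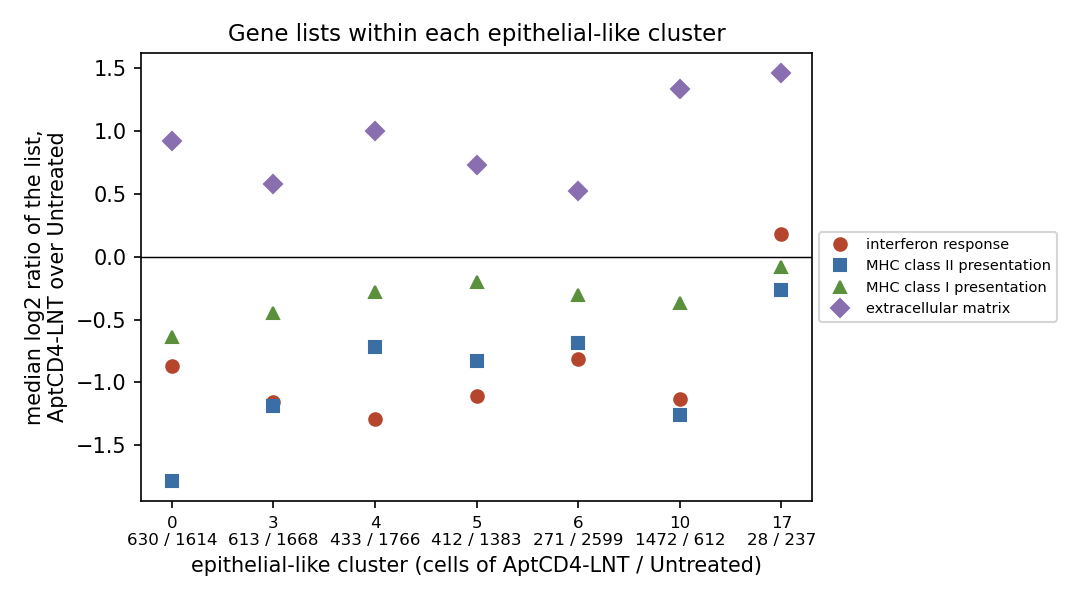
Median log2 ratio of the interferon response, MHC class II, MHC class I and extracellular matrix lists in each of the 7 epithelial-like clusters.

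Extracellular matrix genes were higher in AptCD4-LNT epithelial-like cells, with a median of 0.86, a 1.82-fold higher level (percentile 100, 7 of 11 higher and 0 lower). Fibronectin, Fn1, the most abundant, was at 2770 against 2052 CPM, and the collagen gene Col1a2 3.50-fold higher at 48.8 against 13.9. Fibroblasts make far more of the same collagens. Col1a1 was at 25103 against 23871 CPM in fibroblast-like cells and at 68.0 against 25.8 in epithelial-like cells. It was higher in neutrophil-like cells too, at 170 against 72.8 CPM, and in macrophage-like cells, at 122 against 36.3. The collagen values of epithelial-like cells therefore cannot be told apart from fibroblast RNA. Mesenchymal transition genes had a median of 0.45 (percentile 100, 2 of 9 higher and 0 lower), with the intermediate filament gene Vim at 3542 against 2548 CPM. S100a4, a metastasis-linked calcium binding protein outside the lists, was 2.24-fold higher at 818 against 366 CPM.

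Hypoxia and glycolysis genes were lower in AptCD4-LNT epithelial-like cells, at -0.39 (percentile 0, 4 of 12 lower and 0 higher) but at 0.10 in cluster 3, with the glycolytic enzymes Ldha at 835 against 975 CPM and Pgk1 at 589 against 825, and the hypoxia-induced peptide Adm 2.25-fold lower at 32.4 against 73.0. Immediate early genes were higher, at 0.65 (percentile 100, 9 of 12 higher and 0 lower), with the AP-1 subunits Fos at 2452 against 1992 CPM and Junb at 2242 against 1454. They stood higher beside Nr4a1, at 103 against 36.4 CPM, and with Tnfaip3, a brake on NF-kB signalling, at 165 against 68.6. Chemokine genes were mixed at -0.19 (percentile 0.04, 4 of 15 higher and 6 lower), with the neutrophil attractant Cxcl1 2.14-fold higher at 1393 against 650 CPM and Ccl3 lower at 3.68 against 15.5. The p53 and apoptosis genes were at 0.16 (percentile 93.0, 0 of 12 higher and 1 lower) and angiogenesis genes at -0.11 (percentile 7.82, 0 of 7 either way). Proliferation genes have no direction, at -0.10 (percentile 1.52, 0 of 12 either way) in all epithelial-like cells and 0.29 without cluster 10. H2-Ea and Gbp4, both interferon-induced, were among the largest differences of single genes, at 224 against 716 and 44.3 against 175 CPM.

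Macrophage-like cells of the 2 libraries sat in different clusters. Clusters 13 and 8 held 59.5% and 36.95% of the AptCD4-LNT cells, and cluster 14 held 74.8% of the Untreated cells. Their share, 14.4% against 11.8%, changed sign under 9 other ways of filtering, clustering or naming. For libraries clustered apart and for classing by marker score the interval then included 0. The share was 32.6% against 29.1% of haematopoietic cells, but it has no direction. Hypoxia and glycolysis genes were lower by a median of 1.71-fold, at -0.77 (percentile 0, 8 of 12 lower and 0 higher), with Ldha at 640 against 940 CPM and the oxygen sensor Egln3 at 17.4 against 52.5. Genes of alternative activation split, with a median of 0.71 (percentile 99.85, 4 of 8 higher and 2 lower). The mannose receptor gene Mrc1 was at 490.3 against 273 CPM and Il10, an anti-inflammatory cytokine, 7.80-fold higher (6.25 to 9.81) at 76.4 against 9.79, while the arginase Arg1 was 8.66-fold lower (8.19 to 9.17) at 212.0 against 1836 and the lectin Mgl2 lower at 1.14 against 79.0. Inflammatory macrophage genes had no common direction, at -0.09 (percentile 8.48, 2 of 10 higher and 2 lower), with Il1b level at 2359 against 2356 CPM, Nos2, the nitric oxide synthase, lower at 10.9 against 74.1, and Il12b, a Th1-driving cytokine subunit, higher on 45 UMIs against 1. Chemokines were likewise mixed at 0.23 (percentile 94.5, 4 of 14 higher and 3 lower), with Cxcl2 at 2517 against 2636 CPM and Cxcl3 at 9.77 against 251. Angiogenesis genes had opposed members, at -0.63 (percentile 0.09, 2 of 6 higher and 3 lower), with Vegfa at 167 against 248 CPM, and proliferation genes at 0.50 (percentile 99.5, 4 of 12 higher and 0 lower), with Top2a at 164 against 105, though only at 0.09 when each cell was weighted equally. Immediate early and heat shock genes were higher, at 0.73 (percentile 100, 8 of 12 higher and 0 lower), with Dusp1 at 1904 against 818 CPM and Hspa1a at 125 against 30.4. Outside the lists, Tnfrsf9 was 32.9-fold lower at 7.65 against 252 CPM and the activin gene Inhba lower at 6.19 against 126. Csf2ra, the alpha chain of the GM-CSF receptor, gave 0 against 1318 UMIs, at least 275-fold lower, and gave 0 UMIs in the AptCD4-LNT monocyte-like and neutrophil-like cells as well, at least 63.6-fold and 180.0-fold lower.

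Monocyte-like cells were 224 (2.595%) against 780 (4.25%), a share that reversed under 3 other ways of counting, had an interval that includes 0 under 1 and could not be counted under 4, so it has no direction. Their inflammatory genes were 2.16-fold lower, with a median of -1.11 (percentile 0, 6 of 10 lower and 1 higher), including the interleukin genes Il1a, at 120.1 against 371 CPM, and Il6, at 3.67 against 25.2, with the abundant Il1b at 4776 against 5763. Chemokines had a median of -0.53 (percentile 0, 7 of 15 lower and 2 higher), and Cxcl9, induced by interferon-gamma, was 7.22-fold lower (5.31 to 10.04) at 40.3 against 291 CPM. Ccl22, a fixed marker of dendritic cells, gave 104 against 33 UMIs and Ccl17 1 against 193. H2-Aa stood at 5186 against 5742 CPM here and at 2743 against 2962 in macrophage-like cells. Whether the class holds dendritic cells in a different mix was not tested. Hypoxia genes were at -0.77 (percentile 0, 6 of 10 lower and 0 higher), with Vegfa, the main vessel growth factor, at 248 against 508 CPM among them. Genes of alternative activation were mixed at 0.38 (percentile 90.9, 3 of 6 higher and 2 lower) with Arg1 at 226 against 772 CPM, and immediate early genes at 0.49 (percentile 99.99, 6 of 12 higher and 0 lower). Timd4, a receptor of resident macrophages, was at 143 against 21.9 CPM, and Spp1, which encodes osteopontin, at 856 against 3592.

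Neutrophil-like cells were more frequent in the AptCD4-LNT library, at 24.7% (23.8 to 25.6%) against 16.2% (15.7 to 16.8%), a 1.52-fold higher share (1.44 to 1.61). It reached 2.16 on the log2 scale under a stricter filter, since that filter kept 84.2% of the AptCD4-LNT neutrophil-like cells and 26.0% of the Untreated ones. Their median depth was 1351.5 against 809 UMIs, and barcodes below 500 UMIs were not analysed. The higher share therefore cannot be told apart from a loss of shallow Untreated neutrophil-like cells. Cluster 7 held 80.05% of the AptCD4-LNT and cluster 12 held 73.5% of the Untreated neutrophil-like cells. Chemokine genes were lower, with a median of -0.99 (percentile 0, 8 of 13 lower and 2 higher). Cxcl2, which recruits further neutrophils, was 1.65-fold lower at 15893 against 26265 CPM, Ccl4 was at 1279 against 4052, and Ccl3 and Cxcl3 are leading genes of cluster 12, as is Cd274. Cluster 7 is led by the granule genes Ngp and Retnlg. As a list, granule genes, which are transcribed early in neutrophil maturation, were nevertheless at -1.002 (percentile 0, 4 of 8 lower and 2 higher), with Retnlg at 3416 against 4444 CPM and Camp 3.79-fold lower (3.31 to 4.35), but Mmp8 was higher at 562 against 318. The suppressive neutrophil list centred on -0.09 (percentile 13.2, 1 of 12 higher and 3 lower) with opposed members, since Il1b was higher at 17878 against 11982 CPM, Cd274 3.04-fold lower (2.83 to 3.26) at 336 against 1020, and the prostaglandin synthase Ptgs2 2.15-fold higher at 1151 against 535. Hypoxia genes were at -0.28 (percentile 0.94, 4 of 12 lower and 0 higher) and immediate early genes at 0.46 (percentile 99.7, 6 of 12 higher and 3 lower). The interferon-inducible Ifi27l2a was 5.65-fold higher at 1191 against 211 CPM, and the chemokine Ccl6 9.42-fold lower at 273 against 2567.

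Fibroblast-like cells were 655 (7.59%, 7.04 to 8.17%) against 314 (1.71%, 1.53 to 1.91%), a 4.43-fold higher share (3.87 to 5.085), or 2.41-fold higher, at 9.82% against 4.08%, if a further cluster with myofibroblast genes is counted with them. Mesenchymal genes were higher, at 0.44 (percentile 99.97, 3 of 11 higher and 1 lower), with the matrix protease Mmp3 3.73-fold higher (3.48 to 3.995) at 1566 against 420.0 CPM, whereas extracellular matrix genes were close to level at 0.07 (percentile 98.5, 1 of 11 higher and 0 lower). Chemokines were at -0.41 (percentile 0.06, 3 of 14 higher and 7 lower), split between the monocyte attractant Ccl2, 2.38-fold higher at 2102 against 882 CPM, and the interferon-induced Cxcl9, 16.2-fold lower at 5.46 against 88.6. Proliferation genes were at 0.33 (percentile 99.02, 5 of 12 higher and 0 lower), hypoxia genes at -0.16 (percentile 7.95, 1 of 12 higher and 4 lower), angiogenesis genes at -0.05 (percentile 46.3, 3 of 7 higher and 3 lower), and immediate early genes at 0.07 (percentile 91.7, 2 of 12 higher and 1 lower). Serpinb2, a plasminogen activator inhibitor, was nearly private to the AptCD4-LNT cells, on 6140 UMIs against 1 and in 45.0% of cells against 0.3185%, a ratio of 1694 with an interval of 304 to 66934. The IL-33 receptor gene Il1rl1 was at 332 against 2.36 CPM, and the matrix glycoprotein Thbs4 16.55-fold lower at 51.9 against 859.

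Endothelial-like cells, 58 (0.672%) against 167 (0.911%), showed more angiogenic transcripts, with a median of 0.39 (percentile 99.95, 3 of 9 higher and 0 lower). The tip cell genes Esm1 and Apln were 2.41-fold (2.04 to 2.84) and 1.88-fold (1.65 to 2.14) higher, at 599.7 against 249 and 805 against 429 CPM, and the VEGF receptor Flt1 was level at 1190 against 1213. The fibroblast gene Col1a1 was also higher in these endothelial-like cells, at 733 against 33.3 CPM and in 46.55% against 17.96% of cells. Chemokines were at -0.43 (percentile 0.28, 3 of 11 higher and 3 lower) and at -1.39 when each cell was weighted equally, hypoxia genes at 0.00 (percentile 48.2, 1 of 10 higher and 2 lower), and immediate early genes at 0.22 (percentile 99.2, 0 of 12 either way). Proliferation genes, at -0.57 (percentile 0, 5 of 12 lower and 0 higher), lost their direction when each cell was weighted equally. Serpinb2 was higher here too, on 53 UMIs against 3, a 26.3-fold ratio with an interval of 8.52 to 131.5. Pericyte-like cells showed no detectable difference in share, at 0.568% against 0.480%, a ratio of 1.18 (0.816 to 1.70). Skeletal muscle-like cells were 0 against 16 (0.0873%), where the upper bound for 0 cells is 0.0427%.

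**Figure D4:**
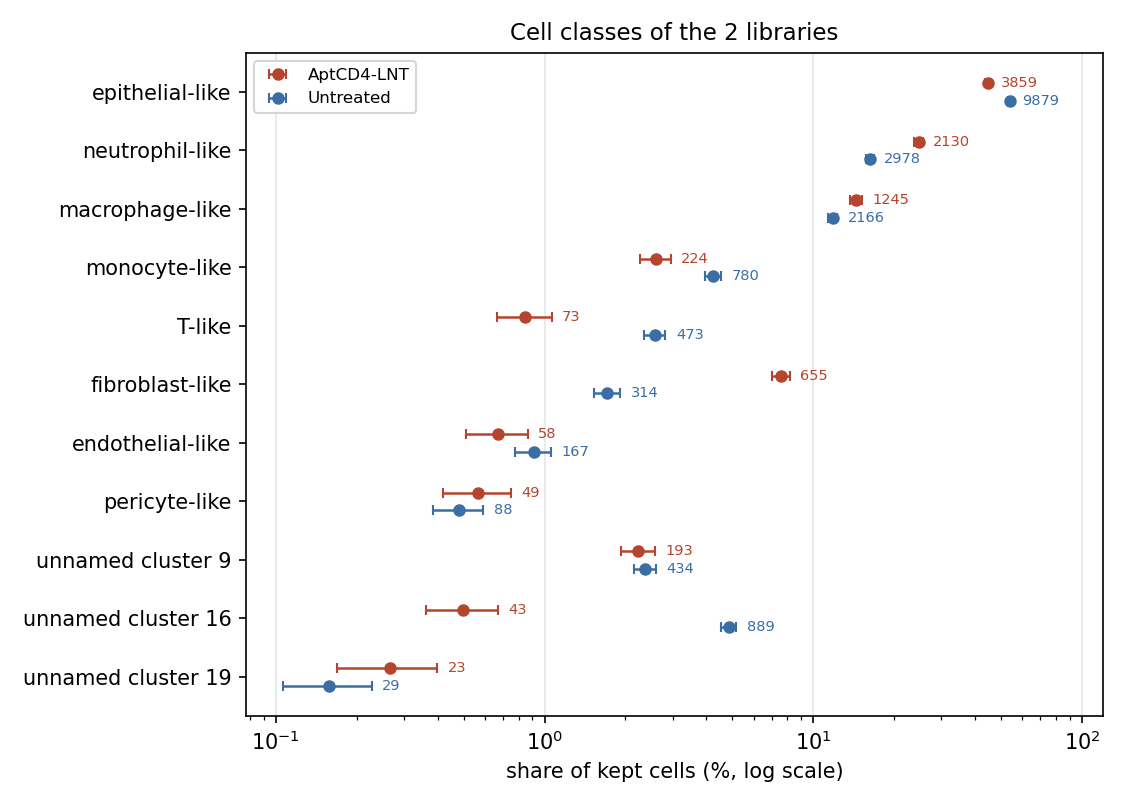
Share of kept cells in each cell class and in the unnamed clusters of the AptCD4-LNT and Untreated libraries, on a log axis with exact 95% intervals. The fibroblast-like share is higher and the T-like share lower in the AptCD4-LNT library.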

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

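Shares were recounted under 2 other filters, 2 other ways of treating doublets, 2 other clustering resolutions, clustering of each library on its own, and classing each cell by its own marker score. Gene lists and genes were recomputed under other scalings, under a mean over cells and, for lists, under other limits on UMIs. Counting the unnamed macrophage clusters, the further fibroblast cluster or the whole T and NK cluster, and leaving out the largest AptCD4-LNT epithelial cluster, were added after the data had been seen. Of the results given in the report, 371 recomputed values stayed within the interval or spread of the value above, with 18 small ones among them crossing 0, and 31 lay outside it, 3 of them with the other sign. A further 13 changed the sign of a difference that had a direction. Of other single genes, 537 stayed, 148 lay outside the interval and 2 reversed. The values below are log2 ratios, and the cause was not tested.

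The macrophage-like share of all kept cells changed sign to -0.28 under the stricter filter, -0.55 without a filter, -0.15 without doublet removal, -0.52 with doublets removed at the expected rate, -0.26 at resolution 0.5, -0.52 at resolution 2, -0.0431 for libraries clustered apart, -0.10 by marker score and -0.15 with the unnamed macrophage clusters. The monocyte-like share changed sign to 0.23 under the stricter filter, 0.24 at the expected doublet rate and 0.93 at resolution 2, and was -0.16 by marker score. It has no value without a filter, without doublet removal, at resolution 0.5 or for libraries clustered apart, where no cluster took that name. The neutrophil-like share was 2.16 under the stricter filter, 0.49 without doublet removal, 1.10 at the expected doublet rate, 1.25 at resolution 2 and 1.24 for libraries clustered apart. In the same order the epithelial-like share was -0.41, -0.17, -0.16, -0.10 and -0.0183. The fibroblast-like share was 2.503 at the expected doublet rate, 1.27 at resolution 0.5, 1.555 by marker score and 1.268 with the further cluster.

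The T-like share was -2.12 for libraries clustered apart and -0.87 for the whole T and NK cluster, and that cluster's share was -1.38 by marker score. The CD4 share of T-like cells changed to -0.37 at the finer split. The stricter filter turned Il23a in T-like cells to -0.85 and Kit in monocyte-like cells to -1.335. Gzmb summed over all barcodes was -1.81.

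With a mean over cells, the proliferation list of endothelial-like cells changed sign to 0.0471, that of macrophage-like cells was 0.08545, macrophage interferon genes -0.52, T-like MHC class I genes 0.13 and endothelial chemokines -1.39. With the median ratio set to 0, macrophage MHC class I was -0.32, macrophage proliferation 0.32 and epithelial MHC class II -1.46. Without the largest AptCD4-LNT cluster, epithelial MHC class II was -1.23, proliferation 0.29, mesenchymal genes 0.28 and immediate early genes 0.38.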

Other observations

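Of the tests in this section, those of library depth, of the mix of epithelial clusters and of matched immediate early genes were written down before their results, and the others were chosen only after the result was seen. The unnamed sub-cluster led by Calca, Il1rl1, Areg and Csf2, which had little Cd3e or Trac, carries genes of group 2 innate lymphoid cells and held 23 AptCD4-LNT against 7 Untreated cells. Mast cell protease genes, chosen after their values were seen, were mostly found in the AptCD4-LNT library, though no mast cell class was named, with Cma1 on 252 against 4 UMIs, Mcpt4 on 106 against 1 and Tpsb2 on 119 against 5 over all barcodes. In the other direction Bglap, the osteocalcin gene, gave 1 against 4488 UMIs, and it leads macrophage cluster 14 of the Untreated library. An unnamed cluster with the osteoclast genes Ctsk, at 11305 against 19830 CPM, and Acp5 held 23 and 29 cells.

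UMIs of Cd3e, which encodes a CD3 subunit of the T cell receptor complex, were not confined to T-like cells. Fibroblast-like cells with a Cd3e UMI were 89 of 655 (13.6%) in the AptCD4-LNT library and 25 of 314 (7.96%) in the Untreated library, yet only 2 and 5 of them had any other T cell gene. Fibroblast-like cells held 49.9% of all Cd3e UMIs of the AptCD4-LNT library against 4.36%, so Cd3e summed over a library does not follow its T cells here. The gene was chosen after its values were seen.

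The T-like share was lower in the AptCD4-LNT library, with a log2 ratio of -1.61. The tables argue against doublet removal taking T-like cells from 1 library, as the ratio was -1.62 (-2.002 to -1.25) without any removal. T-like cells per epithelial-like cell gave -1.34 (-1.72 to -0.98), which argues against dilution by the non-epithelial classes as the whole cause. Whether epithelial-like cells rose in number too cannot be told from shares, so dilution is not excluded. A depth gap between the libraries remains open, because among cells above 0.5 of their library's median UMI count the ratio was -1.53 with an interval of -2.22 to -0.91, on 24 and 168 cells. The treatment itself cannot be told apart from a difference between mice or preparations, with 1 library per group. Cell counts of T cells per tumour from several mice per group would separate these.

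Interferon and MHC genes were lower in AptCD4-LNT epithelial-like cells. The tables argue against macrophage RNA bringing Cd74, which would amount to 25.9 CPM where 1455 CPM was seen (other sources and genes were not tested). They also argue against another mix of epithelial clusters, as the interferon median was -0.82 or lower inside 6 clusters. Cells of 5000 to 15000 UMIs gave -1.02 (-1.31 to -0.83), beside -0.96 over all epithelial-like cells. Their median depth still differed, at 12265 against 8240 UMIs, where all epithelial-like cells had 17350 against 7086. This argues against a depth gap between the libraries as the whole cause, but the smaller gap that remained was not tested. Cells matched on immediate early UMIs gave -0.97 (-1.21 to -0.47), with MHC class II genes at -1.45. This fell short of the bound of -0.5 set for that test and left the immediate early list at 0.19, so it could not decide on a difference in dissociation stress. In cluster 6, chosen after the result was seen, that list was level at 0.03 (-0.39 to 0.17) and the interferon median was -0.82 (-1.18 to -0.68). This argues against dissociation stress as the whole cause in that cluster. The lower Ifng of the whole library, -2.48, and fewer CD8 T-like cells may go with weaker interferon signalling, which was not tested, and the treatment cannot be told apart from a difference between mice with 1 library per group. Interferon-gamma protein in tumours of several mice per group would tell.

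Csf2ra gave 0 UMIs over all barcodes of the AptCD4-LNT library against 3020 in the Untreated library, while Csf2rb, the partner chain, stood at 32.9 against 50.9 CPM. Fewer cells of the classes that hold Csf2ra does not account for it, as 1878 UMIs were expected at the Untreated level of each class, and gene annotations that differ widely between the libraries do not either, as 0 other genes had 0 UMIs in 1 library and 100 or more in the other. A strain or genotype difference at the gene, or a reference that differs there alone, could give 0 UMIs and remains open, because reads over the gene were not analysed here. Aligning the reads of both libraries to the same reference would decide it.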
